A study of Homo sapiens with 3 samples.

How the data were processed

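Total RNA was extracted with Trizol from U2OS cells 5 days after transduction, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. There was 1 array each for stable Set8b, wild-type Set8b and the empty pMSCV vector, and the labels give each array its construct. The deposited values are linear probe-set intensity values, 54675 per array, of which 62 are control probe sets. The software that made them is not given in the sources used here. The values show that every array was scaled to the same trimmed mean of 250.0 (2% trimmed at each end). No detection calls were used here, so signal level alone stood for detection.

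Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The choices below were fixed before the data were examined unless stated otherwise. Deposited values were to be used as they stood if the log2 medians of the arrays lay within 0.1 of each other. They spanned 0.146, so the arrays were quantile normalized. Values were then set to a floor at the 20th percentile (a signal of 7.7) and taken to log2. Control probe sets were left out. Of 54613 other probe sets, 41091 had 1 gene symbol in the platform annotation, 1801 several and 11721 none, and genes were named only from those with 1. Of 41097 entries with 1 symbol, 41043 matched a gene of the RefSeq table of GRCh38.p14 by Entrez identifier, and 0 names differed. That table served for names and for which genes neighbour each other. Probe sets with a mean log2 at or above the median (a signal of 51.4) were kept, 20546 in all, and the brightest one stood for each of 11783 genes.

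Quantile normalization gives the arrays the same distribution, so it removes any overall shift and pulls together the brightest genes. Background on an array can compress the differences of dim genes. Dim signals are also noisier, and a fold can then be too large. With no filter, the SD between probe sets of a gene was 0.746 for wild-type Set8b over vector, against 0.359 with the filter.

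With 1 array per group there is no test. A log2 difference of 2 arrays is given as a value, and genes were counted at a 2-fold difference. For 27 gene lists fixed beforehand, the median difference was set beside 10000 random lists of the same size matched on mean signal in 20 bins, and the central 95% of these is given. This describes these libraries and says nothing about repeats. The lists covered core, linker and replacement histones, histone expression and chaperone factors, histone lysine methylation enzymes, the CRL4-Cdt2 ligase and its substrates, replication, G1/S, mitosis, p53 targets, DNA damage and repair, apoptosis, senescence and secreted factors, interferon response, immediate early genes, unfolded protein and amino acid stress, heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, matrix and bone, Wnt and TGF-beta targets, mesenchymal transition, imprinted genes, and leukocyte and epithelial markers. Of 653 listed symbols, 83 had no probe set with that symbol alone.

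Genes were named by a rule. KMT5A came first. Next were the 10 highest and 10 lowest genes for each comparison of stable Set8b and the 6 highest and 6 lowest for wild-type Set8b over vector, if all their probe sets past the filter went the same way and the chosen one did not end in _x_at. From each list up to 4 members with the largest difference of stable Set8b from vector could be named, and 8 core histones. A few more were named after their values were seen, among them FOS, CDKN1B, COL3A1, MMP3, CHAC1, DDIT4 and ID3. Not every gene that the rule allows is named.

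The steps were tested on simulated data for stable Set8b over vector, with 11795 genes past the filter and noise as wide as the difference between the wild-type and vector arrays. Of 50 genes planted at each size, those past the filter were called in 92.0% (log2 1.5), 93.6% (-1.5), 100.0% (2.5) and 97.7% (-2.5) of cases. Of unchanged genes 99 were called higher and 71 lower. A list of 20 genes shifted by 0.5 reached percentile 100.0, and 6 of 100 unchanged lists fell outside the interval. Chance values for comparisons that share an array came from 100 simulations of unchanged libraries with the same noise.

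Alternatives were values as deposited, arrays centred on their medians, no floor, a floor at the 40th percentile, no filter, the brightest 25% of probe sets, the mean over probe sets, leaving out probe sets ending in _x_at or _s_at, and thresholds of 1.5-fold and 3-fold. A floor at a signal of 50 was added after seeing the data, and differences against a dimmer signal than that are mostly given with that side set to 50. For lists, 1000 simulations of unchanged libraries gave the share of like signs.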

Results

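Expression was measured in U2OS, a human osteosarcoma cell line, 5 days after retroviral transduction with 1 of 3 constructs. The constructs encoded wild-type Set8b, a stable form of Set8b that resists degradation by the CRL4-Cdt2 ubiquitin ligase, or nothing beyond the pMSCV vector. Set8 (gene KMT5A, formerly SETD8) places a single methyl group on lysine 20 of histone H4, and CRL4-Cdt2 marks it for destruction during DNA replication and after DNA damage. Each construct had 1 array, 3 arrays in all, so no difference has a replicate check and no p-value is given. The median probe-set intensity was 41.7 on the stable Set8b array, 42.8 on the wild-type Set8b array and 38.6 on the vector array. After quantile normalization and a filter on dim probe sets, 11783 genes were compared. The only spread at hand was that between probe sets of the same gene on the same arrays, an SD of 0.39 log2 over 5357 genes for stable Set8b over vector. It covers probe noise and not the spread between cultures, and the number of arrays limits the precision of every value.

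KMT5A itself was read by 4 probe sets, which did not move together. Probe set 220200_s_at had a signal of 130.0 with vector, 304 with wild-type Set8b and 243 with stable Set8b, log2 differences over vector of 1.23 and 0.90. For 225118_at the differences were 0.48 with wild-type and 0.38 with stable Set8b, and for 225094_at they were 0.18 and 0.12. The brightest, 228443_s_at, read 428 with vector, 532 with wild-type and 252 with stable Set8b, a log2 difference of -0.76 for stable Set8b over vector. Where these probes lie relative to the transduced sequence was not analysed here, so the probe sets do not check the labels of the libraries. The array labelled stable Set8b also stood apart in its hybridisation spike-ins, whose median ratio over the vector array was 0.796 across 18 probe sets, against 1.01 for wild-type Set8b over vector. The poly-A spike-ins, 24 probe sets, had a median ratio of 0.467 for stable Set8b over vector and 0.441 for wild-type Set8b over vector. For stable over wild-type Set8b the ratio was 1.06, so in these spike-ins the vector array stood apart.

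The comparison of stable Set8b with the empty vector asks what a form of the enzyme that escapes degradation does to gene expression. Targets of the tumour suppressor p53 were higher with stable Set8b, and genes of DNA replication and mitosis were lower. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, read 6589.9 against 1052 with vector, 6.27-fold higher. Of 46 measured replication genes 45 lay below 0, and of 22 measured p53 targets 22 lay above 0. Some secreted factors, such as GDF15 and CXCL8, several histone genes and several collagen genes were also higher. Of the 13 measured genes in the list of senescence and secreted inflammatory factors, not all of them secreted, 7 lay above 0 and 6 below. In total 616 genes were at least 2-fold higher and 567 at least 2-fold lower.

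Among the 22 p53 targets, 14 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.37. Random lists matched on brightness had medians from -0.24 to 0.22 in their central 95%. RRM2B, a p53-inducible subunit of ribonucleotide reductase, was 6.32-fold higher (1793 against 284). ZMAT3 was 5.05-fold higher and all 5 of its probe sets lay between 1.28 and 2.51 log2. TP53INP1 was 4.61-fold higher. The 17 measured apoptosis regulators had a median of -0.05, inside the random interval of -0.32 to 0.29. By the brightest probe set 1 of them passed 2-fold, the survival gene BCL2L1 at 1.12 log2, but its 4 probe sets ranged from 0.32 to 1.94. The 7 probe sets of BCL2L11 ranged from -1.70 to -0.52, so which apoptosis genes pass 2-fold depends on the probe set. BMF was at -0.69 and APAF1 at -0.46.

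Of the 46 genes of origin licensing and replication forks, 21 were at least 2-fold lower and 0 higher, with a median of -0.93 against a random interval of -0.17 to 0.14. MCM7, part of the replicative helicase, read 1547 against 4849 with vector (-1.65), RFC4 of the clamp loader was at -1.57, MCM10 at -1.52 and CLSPN at -1.59, the last 2 by their brightest probe sets, while other probe sets of theirs were at -0.47 and -0.43. The 23 genes of the G1/S transition and nucleotide synthesis had a median of -0.79, with 10 at least 2-fold lower and 1 higher. E2F8, a repressor of the E2F family whose own expression follows the cell cycle, was 7.37-fold lower (72.6 against 535). E2F2 was at -1.71 and CCNE2, cyclin E2, at -1.53. The member that was higher was CCND1, cyclin D1, at 1.63, 3.10-fold.

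Of the 35 genes of G2 and mitosis, 33 lay below 0 and 13 were at least 2-fold lower, with a median of -0.91 against a random interval of -0.19 to 0.15. The mitotic kinase AURKB was 3.63-fold lower, the spindle motor KIF11 3.58-fold lower and the proliferation marker MKI67 3.21-fold lower. CENPF was at -1.44 by its brightest probe set and at 0.44 by its other one, so its direction was not settled. The 29 measured genes of DNA damage checkpoints and repair had a median of -0.51, with 6 at least 2-fold lower and 0 higher. EXO1 was at -1.55, XRCC2 at -1.41 and BARD1 at -1.34. In the list of CRL4-Cdt2 components and substrates, 15 genes, the median was -0.46. KMT5A, the transduced gene, counts in it at -0.76 by its brightest probe set, while its other probe sets were at 0.90, 0.38 and 0.12. The median without KMT5A is not given here. CDKN1A, a substrate, was higher, and the substrates CDT1 and CDC6, both needed to license origins, were at -1.40 and -1.28 (CDC6 at -0.54 by its other probe set). This list is not separate evidence: CDT1, CDC6 and PCNA also stand in the replication list, CDKN1A among the p53 targets, CHAF1A among the histone chaperone factors, E2F1 in the G1/S list and KMT5A among the methylation enzymes.

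**Figure D1:**
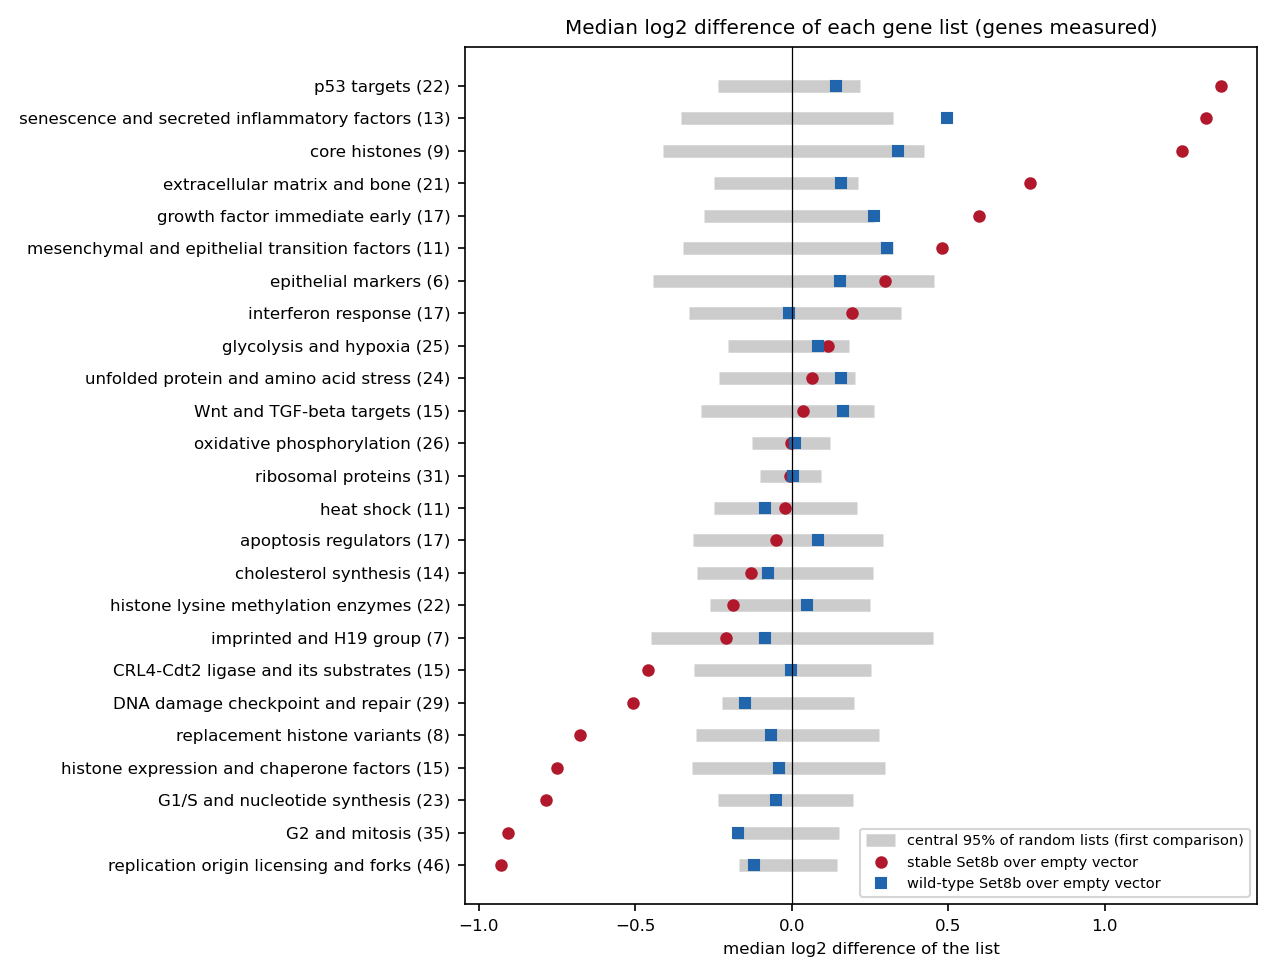
Median log2 difference of each gene list with at least 6 measured members (number in brackets), for stable Set8b over vector (circles) and wild-type Set8b over vector (squares), with grey bars for the central 95% of random lists of the same size and brightness in stable Set8b over vector. The p53 targets lie at 1.37 and the replication genes at -0.93 with stable Set8b, and at 0.14 and -0.12 with wild-type Set8b.

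The core histone genes that passed the filter had a higher median with stable Set8b, while replacement histones were lower. The study's published title names histone gene expression, so this list is not independent evidence of its direction. Of 61 core histone genes listed, 9 passed the filter, and their median was 1.25 against a random interval of -0.41 to 0.42. At least 2-fold higher were 6 of the 9, all but 1 of them H2B genes, led by H2BC9 at 2.01, H2BC5 at 1.84 and H2BC12 at 1.54. H2BC12 read 6316 against 2165 with vector. H2AC14 had a vector signal of 34.0 and was at least 1.04 higher on the log2 scale with that side set to 50, H2BC21 at 1.25 and H2BC6 at 1.05, while H4C8 was at 0.65 and H4C11 at -0.89. Most of these probe sets end in _x_at or _s_at and can also read related histone transcripts, so single histone genes are uncertain. With no filter on dim probe sets the list had 35 members and a median of 0.0.

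The linker histone H1-10 was 3.62-fold lower with stable Set8b (1264 against 4574), H1-2 was at 0.30, and H1-3 read 39.6 against 66.5. The median of -0.75 over 3 genes, just below the random interval of -0.72 to 0.75, is the value of the dim H1-3. With that side set to 50, H1-3 is at -0.41, inside the interval, so no direction is given for the linker histones. All 8 replacement histone variants lay below 0, with a median of -0.68 and 1 of them past 2-fold. That one was H2AX, the variant phosphorylated at DNA breaks, at -1.17, with its 3 probe sets between -2.08 and -0.60. MACROH2A2 was at -0.84, H2AJ at -0.79 and H2AZ2 at -0.74. Of 15 histone expression and chaperone factors, 5 were at least 2-fold lower, and the median was -0.75. They included HJURP, the chaperone of the centromeric histone, at -1.32, CASP8AP2, needed for histone transcription, at -1.19, ASF1B at -1.04 and CHAF1A at -1.03. The 22 histone lysine methylation enzymes and demethylases had a median of -0.19, inside the random interval of -0.26 to 0.25. EZH2 was at -1.44, EHMT2 at -1.38 and NSD2 at -1.10 (6 probe sets between -1.33 and -0.61), and the demethylase KDM5B was higher at 1.16.

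Some secreted factors and matrix genes were higher. In the list of senescence and secreted inflammatory factors, 13 genes were measured, 7 at least 2-fold higher and 1 lower. GDF15, a stress-induced cytokine, was 29.2-fold higher (2122 against 72.6), CCL20 was 8.39-fold and IGFBP7 6.53-fold higher. The neutrophil chemokine CXCL8 read 466 against 19.7, at least 3.22 higher on the log2 scale with the vector side set to 50. GDF15 and CXCL8 were read by _x_at probe sets. The one that was lower was the cell cycle inhibitor CDKN1B at -1.73. The list's median of 1.32 rests on members that went both ways, 7 above 0 and 6 below, and it was -0.03 with no filter, -0.04 among the brightest 25% of probe sets and -0.06 without _x_at and _s_at probe sets. Of 21 measured genes of extracellular matrix and bone, 8 were at least 2-fold higher and 1 lower, with a median of 0.76. COL5A1 was at 1.88, COL11A1 at 1.87, COL6A3 at 1.57 and THBS1 at 1.67, and COL3A1 was the lower one at -1.29, with 4 probe sets between -1.63 and -0.60.

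Among 11 genes of mesenchymal and epithelial transition the median was 0.48. SNAI2, a repressor of epithelial genes, was 5.60-fold higher (951 against 169.9), CDH11 was at 1.29 and CDH2 at 0.75. The 17 immediate early genes had a median of 0.60, with 4 at least 2-fold higher. These were the phosphatase genes DUSP1 at 1.99 and DUSP5 at 1.54, FOSL1 at 1.24 and CCN2 at 1.14. Epithelial markers, 6 genes, had a median of 0.30, inside the random interval. Of these, 4 lay above 0, among them CLDN4 at 0.75, and 2 below, with EPCAM at -1.35. Of the 15 leukocyte markers listed 2 passed the filter, CD3D at 0.90 and CD79A at 0.23.

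Other lists stayed inside the random interval with stable Set8b. The 17 interferon response genes had a median of 0.19, with IFIT1 at -2.14, IFIH1 at -1.07 and ISG20 at 1.13. The 24 genes of the unfolded protein and amino acid responses were at 0.07, with SESN2 at 1.09 and VLDLR at -0.86. The 25 genes of glycolysis and hypoxia were at 0.12, with HK2 at 1.22 and SLC2A3 at 1.09. Heat shock (11 genes, CRYAB at 0.74) was at -0.02, and cholesterol synthesis (14 genes, HMGCS1 at 0.52) was at -0.13. The 26 genes of oxidative phosphorylation had a median below 0.01 in size (-0.004). The 31 ribosomal protein genes were at -0.005, and at -0.23 with values as deposited, since quantile normalization sets the brightest genes of the arrays to equal levels. The 15 Wnt and TGF-beta targets were at 0.04 with members on both sides, LTBP2 at 1.34 and the Wnt feedback genes RNF43 at -1.62 and AXIN2 at -1.28. Imprinted genes (7 measured) were at -0.21, with PEG10 at -1.83.

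The rule for named genes leaves out _x_at probe sets, such as those of GDF15 and CXCL8, from the highest and lowest genes. A signal below 50, close to the filter level of 51.4, may be background. Differences against it are given as at least those with that side set to 50, a floor chosen after seeing the data. Such a bound does not cover noise. SUGCT, which encodes a mitochondrial coenzyme A transferase, read 5183 against 92.5 with vector, 56.0-fold. RGS4, a regulator of G protein signalling, was 17.4-fold higher (4889.5 against 282), and its 3 probe sets lay between 2.19 and 4.12 log2. LINC00520 was at 4.36, CCDST at 3.94 and CCDC148 at 3.80. Against dim vector signals, ODAPH was at least 3.49 higher, CSMD3 3.21, the desmosome protein gene DSP 2.91, CCDC30 2.61 and the trefoil peptide gene TFF2 2.35. Among the lowest were CRISPLD1 at -2.89, E2F8 at -2.88, EP300-AS1 at -2.42 and the phosphatase PTP4A3 at -2.40, with another of its probe sets at -0.52. With the dim stable Set8b side set to 50, the growth factor FGF9 was at -2.16 or lower, ANHX at -1.94, RBM47 at -1.86, MBOAT1 at -1.46, the transcription factor IKZF2 at -1.24 and LINC00992 at -1.02.

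Of the genes at least 2-fold higher that had several probe sets, 90.1% (182 of 202) had all of them on the same side, and of the lower ones 86.8% (165 of 190). Every probe set passed 2-fold for 88 of these 202 and 66 of these 190 genes, so calls of single genes often depend on the probe set. HK2, SLC2A3, LTBP2, THBS1, BARD1 and CDT1, given above by their brightest probe sets, also had one short of 2-fold. The dimmer signal lay below 50 for 15.7% of the higher and 20.1% of the lower genes. The counts depend on the filter, with 252 higher and 273 lower among the brightest 25% of probe sets, where fewer genes are counted.

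**Figure D2:**
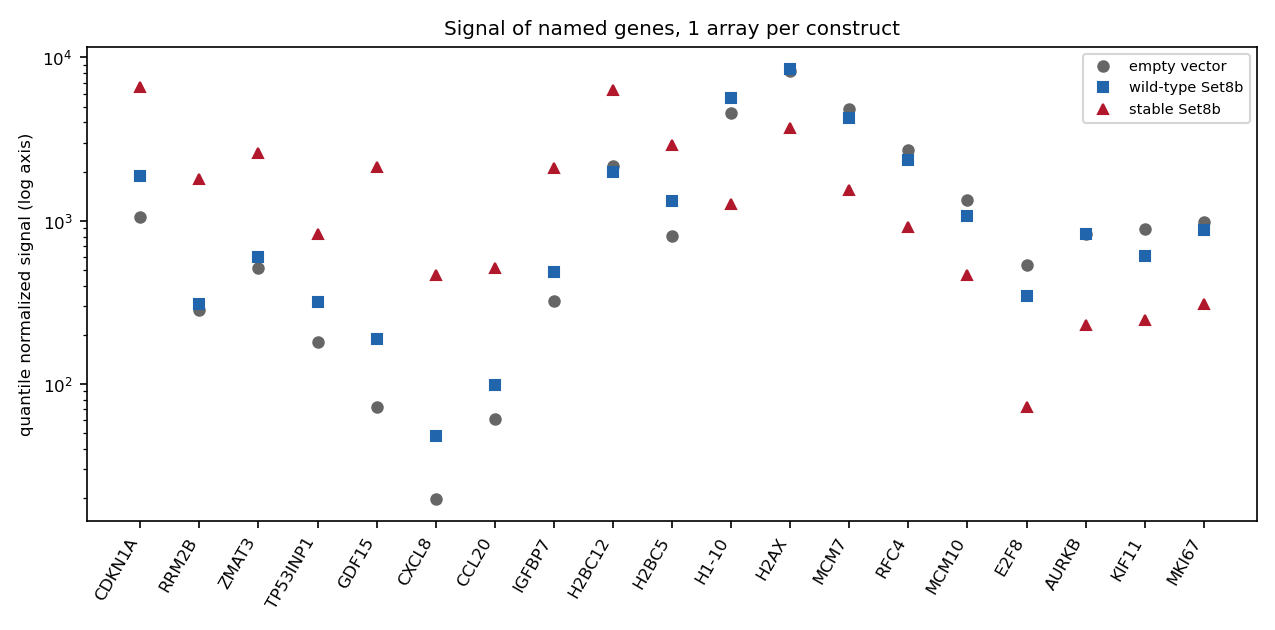
Quantile normalized signal (log axis) of named genes on the vector (circles), wild-type Set8b (squares) and stable Set8b (triangles) arrays, 1 array per construct, with no error bars since there are no replicates. CDKN1A reads 6589.9 with stable Set8b, 1891 with wild-type and 1052 with vector, while E2F8 reads 72.6, 348 and 535.

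The comparison of stable with wild-type Set8b sets the form that resists degradation, labelled Set8_deltaPIP2, beside the degradable one. Whether the altered form differs from wild-type Set8b in more than its stability was not tested. The p53 targets were again higher and the replication and mitosis genes lower, and this comparison uses the same stable Set8b array as the one with vector. The p53 targets had a median of 1.08, with 12 of 22 at least 2-fold higher. RRM2B was 2.53 higher on the log2 scale, ZMAT3 2.12 and CDKN1A 1.80. The replication genes had a median of -0.85 with 18 of 46 at least 2-fold lower, and the G2 and mitosis genes had -0.73 with 9 of 35. Counted over all genes, 524 were at least 2-fold higher and 566 lower.

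Core histones had a median of 0.86, with 3 of 9 at least 2-fold higher, H2BC9 at 2.27, H2BC12 at 1.67 and H2BC5 at 1.14. H4C11 was lower at -1.43, and H2AC14 was at -0.24. H1-10 was at -2.15, and the linker histone median of -1.24 over 3 genes is the value of H1-3, at -0.90 or lower with its dim side set to 50. Replacement variants were at -0.59 and histone expression and chaperone factors at -0.61, with 5 of 15 at least 2-fold lower. The G1/S genes were at -0.81 and the damage and repair genes at -0.44. The CRL4-Cdt2 list at -0.23, which was outside its random interval over vector, and the histone methylation enzymes at -0.20 lay inside theirs. Matrix and bone genes had a median of 0.93. The senescence and secreted factor list had 0.99, with 6 of 13 at least 2-fold higher and 2 lower. That last median was -0.28 among the brightest 25% of probe sets.

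Immediate early genes had a median of 0.35, yet FOS was 2.11 lower on the log2 scale with stable than with wild-type Set8b (122 against 528). FOS and the other genes outside the rule for named genes were picked after their values were seen. Unfolded protein and amino acid response genes were at -0.26, below the random interval of -0.24 to 0.20, with CHAC1 at -1.70, PHGDH at -1.38 and SLC7A11 at -1.08 (-0.29 by another probe set). Glycolysis and hypoxia genes were at 0.25, above their interval of -0.21 to 0.18, with 0 of 25 past 2-fold, and neither list was outside its interval over vector. The mesenchymal list was at 0.30 (SNAI2 at 2.30), inside its interval of -0.36 to 0.30, though it was outside over vector. Interferon response (-0.11), apoptosis regulators (0.11), heat shock (0.10), cholesterol synthesis (-0.11), Wnt and TGF-beta targets (0.08), imprinted genes (-0.24), epithelial markers (-0.07) and leukocyte markers (0.38) lay inside theirs. The heat shock median was -0.05 with values as deposited. Oxidative phosphorylation genes were at -0.07, and ribosomal protein genes at 0.0, or -0.43 with values as deposited.

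SUGCT was at 4.65, LINC00520 at 4.02, CCDST at 3.98, RGS4 at 3.86, CCDC148 at 3.76 and the smooth muscle actin gene ACTA2 at 3.16. With the dim wild-type side set to 50, ODAPH was at least 3.49 higher, DSP 2.91, the serpin SERPINB7 2.89 and the protease inhibitor SPINK6 2.52. The chemokine CXCL14 was at -2.65, CNTNAP2 at -2.56, DYNC1I1 at -2.49 and CRISPLD1 at -2.35. The transcription factor SOX2 was at -2.51 by its brightest probe set but -0.18 by its other. With the dim stable Set8b side set to 50, the hormone FGF21 was at -2.21 or lower, the myosin MYO3A at -1.75, LINC00992 at -1.65, ANHX at -1.60 and PRIMA1 at -1.25. Of genes past 2-fold with several probe sets, every one passed it for 64 of 188 higher and 52 of 193 lower genes. Shared with the comparison against vector were 323 higher and 380 lower genes, where lists drawn independently would share 27.4 and 27.2. Simulated unchanged libraries, which also share the 1 array but give it no more noise than the others, gave 20.1 and 19.7 shared genes on average.

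The comparison of wild-type Set8b with the vector asks what the degradable enzyme does. The differences were smaller than with stable Set8b. None of the p53 targets, replication genes or mitosis genes passed 2-fold. CDKN1A was 0.85 higher on the log2 scale, TP53INP1 0.82 and GDF15 1.39. In all, 120 genes were at least 2-fold higher and 77 lower, and the SD of the log2 differences over all genes was 0.36, against 0.64 for stable Set8b over vector. The SD between probe sets of the same gene was as large, 0.36, and the differences of the brightest and next brightest probe set correlated at 0.181 across genes, against 0.61 for stable Set8b over vector. Most single-gene differences here are therefore not separable from probe noise.

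The list medians were small. Replication genes were at -0.12 (random interval -0.08 to 0.09), G2 and mitosis genes at -0.17 (-0.08 to 0.09) and damage and repair genes at -0.15 (-0.11 to 0.13). The p53 targets were at 0.14 (-0.11 to 0.13) and core histones at 0.34 (-0.22 to 0.25). The senescence and secreted factor list was at 0.50 (-0.18 to 0.20) and immediate early genes at 0.26 (-0.14 to 0.16). Matrix and bone genes were at 0.16 (-0.11 to 0.12) and the mesenchymal list at 0.30 (-0.17 to 0.20). Of the 14 lists outside the interval with stable Set8b, 13 had the same sign here (92.9%). Of these 14, 9 were outside the interval here too (64.3%), where independent calls would give 5.7 lists. The 14 count the linker histones, which were given no direction above and had the other sign here (0.298). Both comparisons subtract the same vector array. In 1000 simulations of unchanged libraries, 79.7% of lists outside their interval had the same sign in the other comparison and 10.9% were outside there too. The simulation draws genes independently, so it leaves out shifts of a whole list on the vector array, and the likeness is no evidence of a weaker effect of wild-type Set8b.

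H2AC14 was the core histone past 2-fold, at least 1.28 higher with its dim vector side set to 50. MMP3, a matrix protease in the senescence and secreted factor list, read 23.3 against 62.1 with vector. FOS read 528 with wild-type Set8b and 230.5 with vector, and the stress genes CHAC1 and DDIT4 of the amino acid response list were at 1.01 and 1.15. That list had a median of 0.16, above its interval of -0.10 to 0.12. KRT14 was at 1.08 in the epithelial list, whose median was 0.16. The BMP target ID3 was at -1.01, while the Wnt and TGF-beta list was at 0.163, just above its interval of -0.127 to 0.156, and at -0.04 with the mean over probe sets, so its direction was not settled. Lists inside their interval were linker histones (0.30), replacement variants (-0.07), histone chaperone factors (-0.04), histone methylation enzymes (0.05), the CRL4-Cdt2 list (-0.004), G1/S genes (-0.05), apoptosis regulators (0.09), interferon response (-0.008), heat shock (-0.09), cholesterol synthesis (-0.08), glycolysis and hypoxia (0.08), oxidative phosphorylation (0.009), ribosomal proteins (0.005), imprinted genes (-0.09) and leukocyte markers (0.19). With values as deposited the replacement variants were at 0.03, the interferon list at 0.01, the heat shock list at 0.002 and the ribosomal proteins at 0.23.

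Of the 12 genes named by size, ZNF319 at 2.15 and the platelet receptor GP6 at -1.94 had both signals above 50. With the dimmer side set to 50, TTC38 was at least 2.03 higher, RASL10A 1.09, CSMD3 0.76, LINC00595 0.66 and IGFL2 0.42. Likewise TOX-DT was at -1.62 or lower, TBKBP1 at -1.48, the noncoding host gene GAS5 at -1.31, the receptor PDGFRB at -1.14 and ACTBP9 at -0.91. PDGFRB read 24.7 with wild-type Set8b, 109 with stable Set8b and 110.0 with vector, and each of these 12 genes had 1 probe set past the filter. Of the genes past 2-fold with several probe sets, 46.2% of the higher (6 of 13) and 61.5% of the lower (8 of 13) had all of them on the same side, and every probe set passed 2-fold for 0 of them. The dimmer signal lay below 50 for 45.8% of the higher and 61.0% of the lower genes. Among the brightest 25% of probe sets 11 genes were higher and 8 lower.

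Across 11783 genes, which are not independent replicates, the differences of stable and of wild-type Set8b from vector had a Pearson correlation of 0.338 and a Spearman correlation of 0.317. Simulated unchanged libraries against the shared vector array gave 0.501. The covariance was 0.0782, against 0.0653 in the simulation, a difference of 0.0129. The comparisons shared 65 genes at least 2-fold higher and 10 lower, where independent lists would share 6.3 and 3.7 and the simulation gave 20.8 and 20.1. Of the 616 genes higher with stable Set8b, 79.5% lay above 0 with wild-type Set8b (median 0.34), and of the 567 lower ones 70.2% lay below 0 (median -0.16). In the simulation, which leaves out any effect and the wider spread of stable Set8b, these shares were 89.5% and 90.1%. Neither the shares nor the overlaps can therefore be set against it as chance values. With 1 vector array the overlap cannot be split, and part of it may come from that array.

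**Figure D3:**
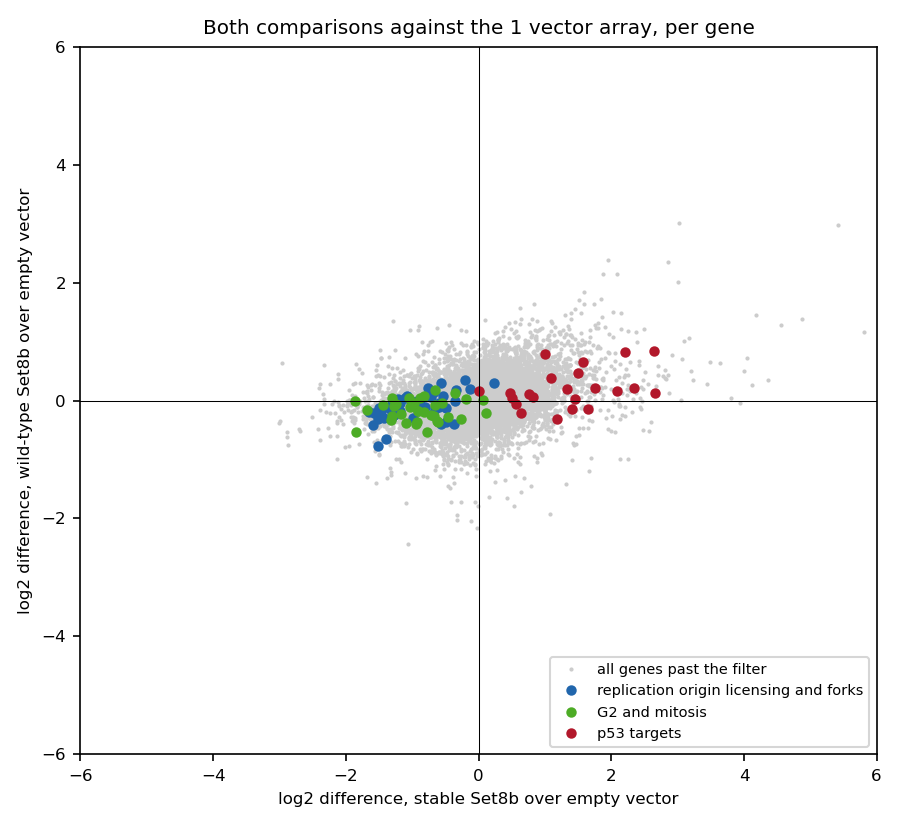
Log2 difference of each of 11783 genes for stable Set8b over vector (x axis) and wild-type Set8b over vector (y axis), with replication, mitosis and p53 genes in colour. The coloured groups separate along x, with medians of -0.93, -0.91 and 1.37, and lie near 0 along y, with medians of -0.12, -0.17 and 0.14.

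Each library was also set against both others at once. With stable Set8b, 323 genes were at least 2-fold above and 380 at least 2-fold below both other arrays. The wild-type array stood apart for 11 higher and 41 lower genes, and the vector array for 10 higher and 65 lower genes. Pearson correlations of log2 signals were taken across the genes past the filter, after quantile normalization. They were 0.945 between stable Set8b and vector, 0.948 between stable and wild-type Set8b, and 0.982 between wild-type Set8b and vector. Across all non-control probe sets with values as deposited, dim ones included, they were 0.901, 0.899 and 0.906. By that measure the stable Set8b array hardly stood apart.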

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

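The tests of array noise, compression, RNA breakdown, shared histone probe sets and cell division were chosen after the results were seen.

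Probe sets outside the gene comparison differed between stable Set8b and vector about as often as the genes did. Of 2773 bright probe sets with no gene symbol, 124 were at least 2-fold higher and 153 at least 2-fold lower with stable Set8b than with vector, against 49 and 54 with wild-type Set8b. Of 1054 with several symbols, 46 were higher and 55 lower, against 9 and 14 with wild-type Set8b. With stable Set8b over vector, 4.47% of those with no symbol were higher and 5.52% lower. For those with several symbols the shares were 4.36% and 5.22%, and for the genes compared 5.23% and 4.81%.

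The stable Set8b array stood apart from both others, with 323 genes at least 2-fold above both and 380 below. Noise of single probe sets was argued against, since the differences of the brightest and next brightest probe set of a gene correlated at 0.61 across genes. Both probe sets were read on the same arrays, so this does not cover the labelling or hybridisation of a whole array. The hybridisation spike-ins of the stable Set8b array had a median ratio of 0.796 over vector and 0.784 over wild-type Set8b. For compression, the count of such genes with values as deposited was 1.013 times that after quantile normalization. This cannot decide, since a shift of bright genes well short of 2-fold may change few counts at 2-fold. The 99th percentile of signal was 8223.9 on the stable Set8b array, 9011.4 on the wild-type array and 8762.5 on the vector array. RNA breakdown was argued against by the 3' over 5' ratios of GAPDH and ACTB, at most 0.95 times the mean of the other arrays. That compares the arrays and does not grade the RNA. On the stable Set8b, wild-type and vector arrays the ACTB ratio was 7.326, 7.563 and 7.995, and the GAPDH ratio 1.022, 1.121 and 1.031. Differences between cultures other than the construct, and differences in how an array was prepared, stay open, as there is 1 array per group. They cannot be told apart from the effect of stable Set8b.

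Core histone genes had a higher median with stable Set8b among the 9 that passed the filter, and a median of 0.0 over 35 with no filter. Probe sets that read several histone transcripts may contribute, and the 2 members read by other probe sets had a median of 1.095, too few to decide. An effect of the construct on these genes stays open too.

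Replication and mitosis genes were lower together. A smaller share of dividing cells is a candidate explanation. The medians of the 2 lists lay 0.023 apart, both below their random intervals, but this restates the pattern and cannot tell that explanation from others. Whether dividing cells were fewer or each made less of these transcripts was not tested.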

How the results depend on the processing

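The floor at a signal of 50 was chosen after seeing the data, and the others were planned.

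No paired analysis was possible because each construct had 1 array. Over all alternatives, 78 gene counts stayed within 1.5 times the count reported and 54 did not. Of list medians 40 changed sign, 6 of them of lists outside their random interval and 34 of lists inside it. Apart from those 6, 707 kept their value within its spread, a change of sign included, and 13 moved. Of single named genes 12 values changed sign, 1 of them of a gene past 2-fold. Apart from that 1, 1282 stayed within the spread and 91 moved. The signal limits what can be seen: with no filter, dim genes near background enter and the counts of every comparison grow. The filters and thresholds change counts by their construction, and for the other changes the cause was not tested. In what follows, counts are higher and then lower genes.

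With no filter the counts were 2032 and 1813 for stable Set8b over vector, 1928 and 1895 for stable over wild-type, and 1465 and 1317 for wild-type over vector. Apart from both others were 1009 and 944 genes for stable Set8b, 601 and 592 for wild-type and 555 and 654 for vector. Among the brightest 25% of probe sets they were 252 and 273, 193 and 258, and 11 and 8, and apart from both others 140 and 195, 2 and 3, and 0 and 6. At 1.5-fold they were 1606 and 1649, 1518 and 1692, and 656 and 484, and apart from both others 985 and 1150, 189 and 223, and 129 and 318. At 3-fold they were 192 and 126, 157 and 134, and 13 and 14, and apart from both others 108 and 89, 0 and 10, and 0 and 11. With the floor at a signal of 50, 44 genes were lower with wild-type than with vector, and 15 and 40 were lower than both others on the wild-type and the vector array. Genes higher on the wild-type array than on both others numbered 20 with values as deposited, 19 with centred arrays and 7 without _x_at and _s_at probe sets.

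The core histone median for stable Set8b over vector was 0.0 with no filter. For stable Set8b over vector, the median of the senescence and secreted factor list changed sign. It was -0.031 with no filter, -0.043 in the brightest 25% and -0.055 without _x_at and _s_at probe sets. For stable over wild-type it was -0.284 in the brightest 25% and -0.387 without _x_at and _s_at probe sets. The list then had 25 members with no filter, 8 in the brightest 25% and 7 without those probe sets, and its members go both ways. The Wnt and TGF-beta median for wild-type over vector was -0.042 with the mean over probe sets, and CENPF was 0.444 by its other probe set. The correlation of both comparisons with vector was 0.425 with no filter. The SD between probe sets of a gene, for stable over vector, stable over wild-type and wild-type over vector, was 0.758, 0.781 and 0.746 with no filter, 0.261, 0.293 and 0.234 in the brightest 25%, 0.405, 0.44 and 0.37 without _x_at and _s_at probe sets, and 0.372, 0.399 and 0.337 with the floor at 50.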

Other observations

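The gene families below were looked at after the results were seen, and the tests of neighbouring genes were planned before theirs.

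Families formed by shared symbol stems showed groups beyond the lists. Of 192 stems with at least 8 measured members, 23 had a median for stable Set8b over vector outside the central 95% of random lists, where chance gives 9.6. The 11 genes of the MCM stem were lowest at -1.22, all below 0. CEP genes of the centrosome (34 members) were at -0.48, led by CEP152 at -1.57, and NUP genes of the nuclear pore (23) at -0.37. COQ genes of coenzyme Q synthesis (11) were at -0.64 with 4 of them above 0, and splicing factors of the SRSF stem (9) at -0.40. Zinc finger genes of the ZNF stem (317) were at -0.12.

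Higher stems were collagens (24 members, median 0.55), RGS genes (11, 0.45), interleukins and their receptors (26, 0.40) and keratins (12, 0.40). IL18 was at 1.66, IL4R at 1.40 and KRT20 at least 2.22 higher with its dim vector side set to 50, while IL11 was at 2.81 by its brightest probe set and -0.11 by another. Olfactory receptor genes (10) had a median of 0.63, with OR51B5 at 2.86, OR51I1 at least at 1.36 in the same way and OR51B4 at 1.00. The direction of each of these stems was the same with values as deposited and with centred arrays. MCM and collagen genes also stand in the lists of the report, so they are not separate evidence.

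Neighbouring genes were counted among the 11775 measured genes placed in the RefSeq gene order, leaving out pairs with the same symbol stem. Adjacent thus means next among measured genes, and unmeasured genes can lie between the partners of a pair. Genes at least 2-fold lower with stable Set8b formed 39 adjacent pairs, where random placements matched on brightness gave 25.4 on average and 16 to 35 in their central 95%. OIP5 and NUSAP1, ESCO2 and PBK, and CENPK and PPWD1 were such pairs. Genes at least 2-fold higher formed 35 pairs, inside the random 20 to 41 (mean 30.1). A candidate explanation for the lower pairs is regulation shared by neighbours, and probes that read overlapping transcripts or antisense partners are another that was not tested.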
